A study of Mus musculus with 12 samples.

How the data were processed

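RNA of sorted mouse T cells was measured on 12 Affymetrix arrays, 3 in each of 4 groups: CD4 effector T cells and nTregs, each cultured with PBS or with 1 µM AzaC. Per the labels, total RNA was labelled with biotin by the WT Pico kit, and the cells were sorted from co-cultures after 2 days of activation and 2 days of treatment. The labels name a sort of CD8 effector T cells too, for which no arrays are part of the series. They do not state whether the 3 replicates of a group came from separate animals or separate cultures, so the p-values measure the spread between these samples, which can be technical in part.

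The deposited table holds log2 values made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no versions. RMA corrects the background, applies quantile normalization across arrays and summarises the probes of a set. The table has 41345 rows, and the array medians lay between 6.67 and 6.80. No pair of arrays was identical. The values were used as deposited.

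Of the 41345 rows, the array's probe table lists 25335; 23521 carry exactly 1 gene symbol, 1814 carry several and 16010 have no name. Rows with exactly 1 symbol were kept, and for the 1082 genes with several rows the row with the highest mean over all arrays was taken, which left 22180 genes. Of the kept identifiers, 193 were absent from the reference gene table, and 0 symbols needed updating. No filter on dim genes was applied. The genome build behind the authors' annotation is not given in the sources used here, and no coordinates are reported.

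A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 for the random block), which left 8 residual degrees of freedom, and the variances were moderated by limma's empirical Bayes step (prior degrees of freedom 5.95). The 5 comparisons were AzaC minus PBS in nTregs, AzaC minus PBS in CD4 cells, the difference between these effects (the interaction), and nTregs minus CD4 cells under PBS and with AzaC. A gene passed, or was called, at a Benjamini-Hochberg adjusted p under 0.05 over all genes. All adjusted p-values of single genes come from limma. With 3 arrays per group, the median SE of a log2 difference was 0.13, and 0.18 for the interaction, and this number of arrays limits the precision of each value. All genes had a median difference of −0.04 in nTregs and 0.01 in CD4 cells. At an unadjusted p under 0.05 in limma stood 3720 of the 22180 genes in nTregs, 3375 in CD4 cells and 3871 for the interaction. Counts of list genes at that level are to be read against these shares of all genes.

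Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with the Benjamini-Hochberg adjustment over the lists of a comparison, and beside it with camera at an estimated correlation and with fry. The 24 lists were germline genes silenced by DNA methylation, imprinted genes, DNA methylation machinery, azacitidine uptake and metabolism, interferon-stimulated genes, p53 target genes, DNA damage repair, G1/S genes, G2/M genes, Treg signature, effector cytokines and chemokines, cytotoxic effectors, lineage transcription factors, naive and memory T cell genes, costimulatory and inhibitory receptors, apoptosis regulators, immediate early and stress genes, glycolysis and cholesterol synthesis, and markers of CD8 T cells, B cells, myeloid and dendritic cells, NK and gamma-delta T cells, erythroid cells and platelets, and mitochondrially encoded RNAs. Lists with at least 5 measured genes were tested, which excluded the CD8 markers and left 23. Some genes stand in more than 1 list.

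The genes named were fixed by rule: the 10 largest rises and 10 largest falls among called genes whose group values did not overlap (5 and 5 for nTregs against CD4 cells with AzaC, and the adjusted p alone for the interaction), up to 4 genes per list with the smallest p, and 15 genes in every comparison. Predicted gene models, small RNAs, T cell receptor and immunoglobulin segments and histone cluster genes were passed over; these were 2 of the falls in nTregs, 3 of the rises in CD4 cells, 3 negative interactions, 2 genes higher in nTregs under PBS, and 2 higher and 1 lower with AzaC. The comparisons, tests, thresholds, lists, naming rule and most alternatives were chosen before the data were examined. Overlaps between the AzaC responses were tested with Fisher's exact test over the 22180 genes. The comparison of CD4 cells with and without AzaC shares its PBS arrays with that of nTregs and CD4 cells under PBS, so no overlap of their calls was computed.

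The alternatives were a filter on dim genes, centring or repeated quantile normalization, leaving out each array in turn, the mean over a gene's rows, every row of the table, a fit of only the groups compared, fixed and random blocks for same-numbered arrays, array weights, a variance trend with robust moderation, a test without moderation, and a fold change of at least 1.5. A fit without the arrays nTreg PBS 1 and CD4 PBS 3 was added after their low weights were seen. The fitting steps were tested on simulated data of 22180 genes with known changes. The noise was normal, independent between genes, and of the same spread in every array. The simulation thus held no correlated genes and no deviating array, and its recovery rates may differ from those of the real arrays.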

Results

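Gene expression was measured on 12 Affymetrix arrays hybridised with RNA from activated mouse T cells. Natural regulatory T cells (nTregs, CD4 T cells defined by the transcription factor Foxp3) and Treg-depleted T cells marked by the red fluorescent protein DsRed were grown together at 1 part to 10 parts. The cultures were activated for 2 days with beads against CD3 and CD28 and with interleukin-2, and then kept for 2 more days with 1 µM azacitidine (AzaC) or with PBS. AzaC is a cytidine analogue that is built into nucleic acids and inhibits DNA methyltransferases. Cells were sorted on DsRed and on a green reporter of Foxp3. The nTregs were DsRed negative and reporter positive, and the CD4 effector T cells, called CD4 cells here, were DsRed positive and reporter negative. There were 3 arrays in each of 4 groups, and the median signal of an array lay between 6.67 and 6.80 on the log2 scale. The series title names graft-versus-host disease and the expansion of nTregs as its subject. The arrays answer which genes AzaC changed in each population.

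In nTregs, AzaC changed 448 of 22180 genes, of which 315 rose and 133 fell. Il23r, a subunit of the interleukin-23 receptor, rose from 4.91 ± 0.41 (SD, n = 3) on the log2 scale under PBS to 7.26 ± 0.37 with AzaC (log2 difference 2.35, SE 0.20, adjusted p = 5.18e-05). Its PBS signal, like that of Csn2 (4.64 ± 0.15), lay near that of the germline gene Asz1 (4.56 ± 0.05). Both lay above the fifth percentile of the nTreg PBS arrays (3.51 to 3.62), and whether they are background was not tested. The sizes of both differences are therefore not exact and may be too small. Plagl1, an imprinted gene for a zinc finger transcription factor, rose 4.93-fold, from 6.77 ± 0.12 to 9.07 ± 0.17 (SE of the log2 difference 0.12, adjusted p = 2.62e-07). Nfkb2, a subunit of the transcription factor NF-kB, rose by 1.71 (SE 0.20), from 9.09 ± 0.51 to 10.80 ± 0.13. Fam183b showed the largest fall among the named genes, from 10.59 ± 0.43 to 8.29 ± 0.11 (log2 difference −2.30, SE 0.22, adjusted p = 9.66e-05).

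Other large rises in nTregs were those of Csn2 (the milk protein beta-casein, 2.04), Ly6g5b (1.91), Atp8b4 (a phospholipid-transporting ATPase, 1.73), Dusp4 (a MAP kinase phosphatase, 1.72), Odc1 (the first enzyme of polyamine synthesis, 1.64), Scin (an actin-severing protein, 1.55) and Tmem176a (1.54), with SEs of 0.14 to 0.22. Next to Fam183b, the largest falls were Muc3a (a mucin, −1.35), Prg4 (lubricin, −1.23), Slc25a33 (a mitochondrial pyrimidine nucleotide carrier, −1.15), Clybl (a mitochondrial lyase, −1.15), Gpr155 (−1.07), Mirt1 (−0.99) and Fxyd7 (−0.95). Chil5 fell too (−1.12), but its signal with AzaC (4.95) lay near that of the germline gene Asz1, so the size of its fall is not exact and has no rank. Of the 448 genes, 71 changed at least 2-fold, 61 higher and 10 lower. Group values without overlap were found for 24.5% of all genes, where chance gives 10% with 3 arrays against 3.

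**Figure D1:**
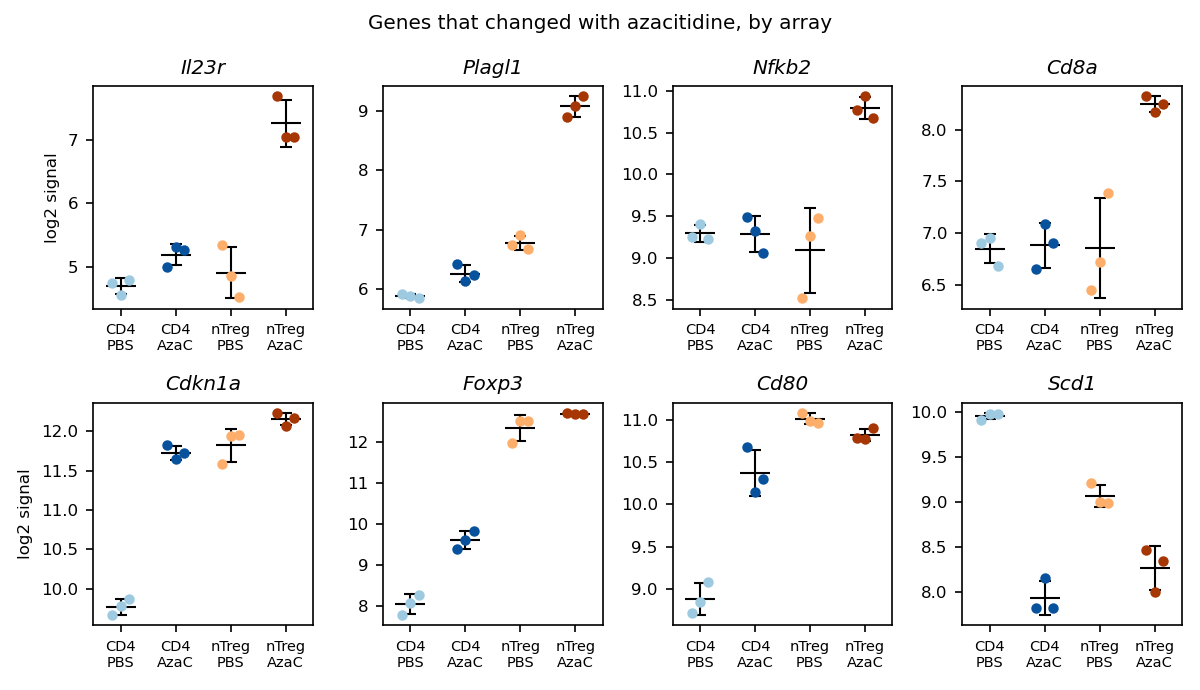
Log2 signal (vertical axis) of 8 genes in each of the 12 arrays, by group (horizontal axis); points are single arrays, and the horizontal line and bars give the mean and SD of 3 arrays. Il23r, Plagl1, Nfkb2 and Cd8a are higher in the 3 nTreg arrays with AzaC than in any other array, while Cdkn1a, Foxp3 and Cd80 rise and Scd1 falls in CD4 cells.

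Among the gene lists, those of immune effector functions moved upward in nTregs. Of 20 cytotoxic effectors, 5 rose and 15 did not pass (9 rose when adjusted over the list alone). Gzmc, a granzyme, rose by 1.03 and Ctsw, cathepsin W, by 0.70. The list passed the camera test (median 0.36, adjusted p = 1.43e-06; adjusted p = 0.135 with an estimated correlation). The CD8 T cell markers Cd8a and Cd8b1 rose in the same comparison, and CD8 T cells express cytotoxic effectors too. The nTregs were sorted as DsRed negative and Foxp3 reporter positive, a gate against the DsRed-marked T cells of the cultures. How many such cells passed the gate was not measured, so CD8 T cells as a source of this rise were not excluded. Of 27 effector cytokines and chemokines, 6 rose (8 adjusted over the list alone), including Tnf (tumour necrosis factor, 1.05), Cxcl10 (1.03) and Xcl1 (0.92). The cytokine list had a median of 0.02 and a mean of 0.21 (adjusted p = 0.00263; adjusted p = 0.187 with an estimated correlation). Of 29 genes of the Treg signature, 5 rose, 1 fell and 23 did not pass (10 and 1 adjusted over the list alone; median 0.30, adjusted p = 1.04e-07; adjusted p = 0.145 with an estimated correlation). Itgae, the integrin CD103, rose by 0.96 (SE 0.10) in that list, beside Plagl1. The other 4 changes of the list were each lost without at least 1 array, among them that of Ikzf4 (0.76; adjusted p = 0.0686, 0.0650 and 0.0560 without nTreg AZA 1, 2 and 3). Foxp3 itself differed by 0.35 (SE 0.16, adjusted p = 0.294), and Il2ra, Ikzf2 and Ctla4 by 0.26, 0.30 and 0.14, none past the threshold.

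Of 23 costimulatory and inhibitory receptors, 4 rose and 1 fell (8 and 3 adjusted over the list alone). Cd86, a ligand of CD28 and CTLA-4, led them (0.99, SE 0.13). The list median was 0.07 (adjusted p = 0.0271; adjusted p = 0.129 with an estimated correlation). Of 23 apoptosis regulators, 4 rose (4 adjusted over the list alone). Birc2 (0.68) and Birc3 (0.59) among them inhibit apoptosis in TNF receptor signalling (list median 0.09, adjusted p = 0.0117; adjusted p = 0.129 with an estimated correlation). Of 23 lineage transcription factors, Batf3 (1.14) and Eomes (0.96) rose (3 adjusted over the list alone; median 0.11, adjusted p = 0.0134; adjusted p = 0.258 with an estimated correlation). Of 26 interferon-stimulated genes, Cxcl10 alone rose over all genes, while 4 rose and 2 fell adjusted over the list alone (median 0.20, adjusted p = 0.00263; adjusted p = 0.116 with an estimated correlation). These list calls rested in part on single arrays: adjusted p was 0.107 for the receptors and 0.287 for the lineage factors without nTreg PBS 1, and 0.0502 for the apoptosis regulators without nTreg PBS 3.

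Cell cycle lists moved apart in nTregs. Of 24 G1/S genes, 2 rose (2 adjusted over the list alone), with Tk1, a thymidine kinase, at 0.75 (SE 0.11; list median 0.25, adjusted p = 1.43e-06; adjusted p = 0.129 with an estimated correlation). Of 25 G2/M genes, 2 fell (5 adjusted over the list alone; median −0.22, adjusted p = 1.80e-05; adjusted p = 0.249 with an estimated correlation). The call of Mcm2 (0.69) was lost without nTreg AZA 1, 2 and 3 (adjusted p = 0.0525, 0.0746 and 0.0581), and that of Bub1 (−0.52) without the same arrays (0.0577, 0.136 and 0.0954) and without nTreg PBS 1 (0.0547). The proliferation marker Mki67 differed by −0.04 (SE 0.11). The p53 target list was called (median 0.05, adjusted p = 0.0397; adjusted p = 0.423 with an estimated correlation) although limma passed 0 of its 23 genes (9 at an unadjusted p under 0.05, and 5 higher and 2 lower adjusted over the list alone). Without nTreg PBS 1 its adjusted p was 0.762 and its median −0.02, and without nTreg AZA 2 its adjusted p was 0.126.

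Markers of other cells moved in nTregs as single genes. Of the 2 markers of CD8 T cells, Cd8a rose by 1.39 (SE 0.19, adjusted p = 0.0018), from 6.86 ± 0.48 to 8.24 ± 0.08, and Cd8b1 by 0.72 (adjusted p = 0.0213; 0.0547 without nTreg PBS 1, and 0.0800, 0.0618 and 0.0974 without nTreg AZA 1, 2 and 3). Of 21 myeloid and dendritic cell markers, 3 rose and 1 fell (list median −0.13, adjusted p = 0.640). The class II MHC genes H2-Aa and H2-Eb1 rose by 1.36 and 0.71 (adjusted p = 0.0603 for H2-Eb1 without nTreg AZA 1). Among 19 naive and memory T cell genes, Il7r (the interleukin-7 receptor, 0.59) rose and Ly6c1 (−0.94), Klf3 (−0.70) and Slamf6 (−0.59) fell (2 rose and 3 fell; median −0.06, adjusted p = 0.163; 0.00447 without nTreg PBS 1).

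Lists tied to the drug itself did not pass in nTregs. Among 24 germline genes silenced by DNA methylation, limma passed 0 (4 at an unadjusted p under 0.05; median −0.06, adjusted p = 0.498, fry adjusted p = 0.372). The 4 of 24 were near the share of all genes at that level (3720 of 22180). Dnmt1 (0.33, SE 0.18), Dnmt3a (0.30), Dnmt3b (0.30) and Uhrf1 (0.64) did not pass, in a DNA methylation machinery list with a median of 0.15 (16 genes, adjusted p = 0.0732). Without nTreg PBS 2, the adjusted p was 0.0422 for that list and 0.0375 for Uhrf1. Azacitidine uptake and metabolism (18 genes, median 0.06, adjusted p = 0.176) and DNA damage repair (22 genes, 0.01, 0.640) were not called. Neither were glycolysis and cholesterol synthesis (19 genes, 0.03, 0.645), erythroid and platelet markers (7 genes, −0.19, 0.0619) or mitochondrially encoded RNAs (10 genes, −0.15, 0.0602). The erythroid list passed without nTreg PBS 2 (0.0484), nTreg AZA 2 (0.0484) or nTreg AZA 3 (0.0391). The mitochondrial list passed without CD4 AZA 2 (0.0366), nTreg PBS 2 (0.0422), nTreg PBS 3 (0.0239), nTreg AZA 1 (0.0319) or nTreg AZA 3 (0.0329). Without nTreg PBS 1 the glycolysis and cholesterol list was called lower (median −0.13, adjusted p = 0.0104). Imprinted genes (20 genes, 1 called, Plagl1; median −0.04, adjusted p = 0.577), immediate early and stress genes (25 genes, −0.04, 0.645), B cell markers (13 genes, −0.02, 0.645) and NK and gamma-delta T cell markers (8 genes, −0.01, 0.640) had medians below 0 with means and test directions above 0.

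In simulated data for this comparison, 87% of genes changed by 1 on the log2 scale and 35% of those changed by 0.5 were recovered (200 changed of 22180 genes). Without nTreg AZA 1, 2 or 3 the count of 448 became 186, 187 or 186. Of 58 named genes that passed, 37 kept their call without each of the 12 arrays in turn. With every array centred on its median the split was 394 higher and 84 lower (82.4% higher, against 70.3%), and with array weights 767 and 523 (59.5%). The array nTreg PBS 1 stood apart from the rest and deviated from its group mean by an SD of 0.257 on the log2 scale. Its mean correlation with the other arrays was 0.961, against 0.970 for CD4 PBS 3 and 0.977 to 0.982 for the remaining 10. Without nTreg PBS 1, 410 genes were called, 291 of them among the 448.

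In CD4 cells, AzaC changed 391 genes, of which 184 rose and 207 fell. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose 3.87-fold, from 9.78 ± 0.10 (SD, n = 3) to 11.73 ± 0.09 (log2 difference 1.95, SE 0.12, adjusted p = 2.61e-06). Foxp3 rose 2.96-fold, from 8.05 ± 0.24 to 9.62 ± 0.23 (1.57, SE 0.16, adjusted p = 0.000207), against 12.34 ± 0.31 in nTregs under PBS. Cd80, a costimulatory ligand of CD28 and CTLA-4, rose from 8.88 ± 0.19 to 10.37 ± 0.27 (SE of the log2 difference 0.14). Scd1, which introduces the double bond into fatty acids, showed the largest fall of the named genes, from 9.95 ± 0.04 to 7.93 ± 0.19, and fell by 2.02 on the log2 scale (SE 0.13, adjusted p = 4.88e-06).

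Further rises in CD4 cells were Dglucy (1.62), Ptpn14 (a tyrosine phosphatase, 1.51), Tnfsf4 (OX40 ligand, 1.45), Myl10 (1.43), Cdk6 (a G1 cyclin-dependent kinase, 1.38), Trp53cor1 (a p53-induced non-coding RNA, 1.30) and Cpt1c (1.28). Further falls were Aldoc (the glycolytic enzyme aldolase C, −1.69), Fam183b (−1.41), Klrd1 (the NK receptor CD94, −1.35), Cnga1 (−1.29), P4ha2 (a collagen prolyl hydroxylase, −1.22), Trappc6a (−1.21), Idh1 (isocitrate dehydrogenase, −1.21) and Clybl (−1.21), with SEs of 0.11 to 0.25. At least 2-fold changes were found for 57 genes, 32 higher and 25 lower, and group values did not overlap for 23.6% of all genes (10% by chance).

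Of 23 p53 target genes, 8 rose in CD4 cells and 15 did not pass (8 rose and 1 fell adjusted over the list alone; median 0.30, adjusted p = 8.83e-07; adjusted p = 0.182 with an estimated correlation). Beside Cdkn1a they included Tnfrsf10b (a TRAIL receptor, 1.05), Zmat3 (0.99) and Ccng1 (cyclin G1, 0.67). Of 19 genes of glycolysis and cholesterol synthesis, 5 fell (8 adjusted over the list alone; median −0.42, adjusted p = 2.84e-09; adjusted p = 0.237 with an estimated correlation). Fdps (farnesyl diphosphate synthase, −1.04, SE 0.10), Sqle (squalene epoxidase, −0.81) and Cyp51 (−0.72) belong to cholesterol synthesis and Pgk1 (−0.67) to glycolysis. Cyp51 was lost without CD4 PBS 3 (adjusted p = 0.0654) or CD4 AZA 1 (0.0783), and Pgk1 without CD4 AZA 1 (0.0538). Split after the values were seen, the 8 cholesterol genes had a median of −0.59 with 4 lower, and the 11 glycolysis genes a median of −0.22 with 1 lower.

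Of 29 Treg signature genes, 4 rose in CD4 cells (9 rose and 1 fell adjusted over the list alone): Foxp3, Ikzf4 (a partner of Foxp3, 0.98), Il2ra (the interleukin-2 receptor alpha chain, 0.59) and Tnfrsf4 (OX40, 0.56). The list's median was 0.18 (adjusted p = 9.53e-05; adjusted p = 0.293 with an estimated correlation), and Ctla4 (−0.16) and Ikzf2 (0.06) did not pass. Of 27 cytokines and chemokines, 4 rose (6 adjusted over the list alone), including Tnf (1.12), Tnfsf8 (CD30 ligand, 1.06) and Lta (lymphotoxin alpha, 0.80). Their median was 0.18 (adjusted p = 7.93e-05; adjusted p = 0.182 with an estimated correlation). Of 19 naive and memory genes, 3 fell and 1 rose (9 and 1 adjusted over the list alone; median −0.32, adjusted p = 8.83e-07; adjusted p = 0.135 with an estimated correlation). Il7r fell there by 0.61 on the log2 scale (SE 0.09), and Cd27 stood at −0.63 (adjusted p = 0.0581 without CD4 PBS 1 and 0.0562 without CD4 AZA 1).

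Among 24 G1/S genes, 3 rose in CD4 cells (6 adjusted over the list alone; median 0.21, adjusted p = 3.35e-05; adjusted p = 0.196 with an estimated correlation). All 3 were lost without at least 1 array, as was Cdc6 (0.64) without CD4 PBS 1 and 2 (adjusted p = 0.0639 and 0.0708) and CD4 AZA 2 and 3 (0.0595 and 0.0714). The G2/M list was called lower (median −0.22, adjusted p = 4.35e-06; adjusted p = 0.284 with an estimated correlation), although limma passed 0 of its 25 genes (7 at an unadjusted p under 0.05, and 0 adjusted over the list alone). Imprinted genes shifted upward as a list (20 genes, median 0.13, adjusted p = 0.0256; adjusted p = 0.284 with an estimated correlation; 0.137 without CD4 PBS 3 and 0.120 without CD4 AZA 1), with 0 passing limma's test (3 at an unadjusted p under 0.05, and 0 adjusted over the list alone). The 3 of 20 were near the share of all genes at that level in CD4 cells (3375 of 22180).

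Of the drug's targets and enzymes, Hells (a chromatin remodeller of DNA methylation, 0.63) and Dctd (deoxycytidylate deaminase, 0.74) rose in CD4 cells. Their lists of machinery (16 genes, median 0.06, adjusted p = 0.577) and of uptake and metabolism (18 genes, 0.05, 0.627) were not called, and Dnmt1 (0.22), Dnmt3a (0.10), Dnmt3b (0.08) and Uhrf1 (0.19) did not pass. Among 24 germline genes limma passed 0 (2 at an unadjusted p under 0.05; median 0.03, adjusted p = 0.577). Gzmb (granzyme B, 0.77) rose in a cytotoxic list that was not called (20 genes, median 0.10, adjusted p = 0.446; 0.0449 without CD4 AZA 1). Not called either were interferon-stimulated genes (26 genes, 0.08, 0.102), DNA damage repair (22 genes, 0.02, 0.577), apoptosis regulators (23 genes, 0.03, 0.627), B cell markers (13 genes, 0.12, 0.262), NK and gamma-delta T cell markers (8 genes, 0.15, 0.232), erythroid and platelet markers (7 genes, 0.01, 0.649) and mitochondrially encoded RNAs (10 genes, 0.19, 0.157). Interferon-stimulated genes passed without CD4 PBS 3 (0.0341) or CD4 AZA 1 (0.0290), and mitochondrially encoded RNAs without CD4 AZA 2 (0.00787). In 4 lists that were not called, the median differed in sign from the mean and the test: lineage transcription factors (0.01 against a mean of −0.04, adjusted p = 0.494), immediate early and stress genes (0.02 against −0.06, 0.446), myeloid and dendritic cell markers (0.03 against −0.05, 0.627) and costimulatory and inhibitory receptors (−0.05 against 0.05, 0.704). Cd8a (0.03) and Cd8b1 (−0.28) did not pass.

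The count of 391 genes in CD4 cells became 202, 188 and 213 without CD4 PBS 1, 2 and 3, 164 and 171 without CD4 AZA 1 and 3, and 1044 (368 higher, 676 lower) without nTreg PBS 1, which enters through the shared estimate of the spread. Of 49 named genes that passed, 34 kept their call without each array in turn, and centring the arrays gave 132 higher and 351 lower (27.3% higher, against 47.1%). The larger side turned over every row of the table (145 higher, 110 lower), without CD4 PBS 3 (126 and 87) and without CD4 AZA 1 (100 and 64), so neither direction prevailed.

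**Figure D2:**
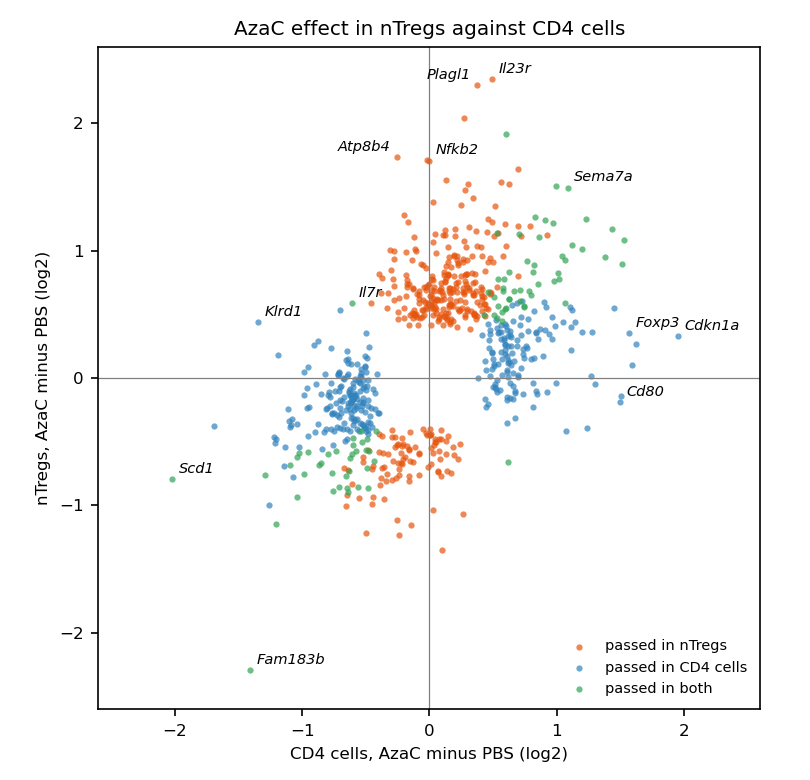
Log2 difference between AzaC and PBS in CD4 cells (horizontal axis) and in nTregs (vertical axis) for the 751 genes that passed in at least 1 population; each point is 1 gene, coloured by where it passed, with 3 arrays per group behind each difference. Genes that passed in both lie along the diagonal apart from Il7r and 1 other gene.

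Part of the response was shared between the populations. In both, 50 genes rose, where 2.61 would be shared by independent lists (Fisher's exact test p = 5.4e-50), and 36 fell, against 1.24 (p = 6.74e-43). The comparisons have no array in common, but both populations were sorted from co-cultures, so differences between cultures can enter both. Fisher's test also takes genes as independent, so its p does not measure replication over cultures. Shared rises were Myl10 (1.17 in nTregs, 1.43 in CD4 cells), Tnf (1.05 and 1.12), Cdk6 (0.95 and 1.38), Ptpn14 (0.90 and 1.51) and Ly6g5b (1.91 and 0.60), and shared falls were Fam183b (−2.30 and −1.41), Clybl (−1.15 and −1.21), Scd1 (−0.79 and −2.02) and Cnga1 (−0.76 and −1.29). Across the 751 genes called in either population, which are not independent replicates, the differences had a Pearson correlation of 0.517, and across all genes of 0.0841. Of the 448 nTreg calls, 76.6% had the same sign in CD4 cells, and of the 391 CD4 calls, 82.9% had the same sign in nTregs. Rises in nTregs that fell in CD4 cells numbered 1, Il7r, against 2.94 for independent lists (Fisher's exact test p = 0.949).

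The difference between the AzaC effects was tested as the interaction of drug and population, with 45 genes passing, 32 more positive and 13 more negative in nTregs. Cdkn1a rose by 1.62 less in nTregs (interaction −1.62, SE 0.16, adjusted p = 0.00126), where it stood at 11.82 ± 0.21 (SD, n = 3) under PBS and 12.15 ± 0.08 with AzaC. Cd80 differed by −1.69 (SE 0.19, adjusted p = 0.00195), with 11.01 ± 0.07 and 10.82 ± 0.07 in nTregs. Plagl1 (1.92, SE 0.16), Atp8b4 (1.99, SE 0.24), Nfkbie (an inhibitor of NF-kB, 1.39, SE 0.15) and Il7r (1.20, SE 0.13) were more positive in nTregs. These 6 kept their call without each array in turn. The other 17 named genes lost theirs without at least 1 array. Dcxr lost it without each of the 12, Birc2, Dusp4 and Ubd without 11, and Cd81, Ddias, Gpr155, Muc3a and Slc19a2 without 10. It was lost for Cd86, Cox6b2 and Nfkb2 without 9 and for Csn2, Dglucy and Scin without 7. The fewest losses were those of Klrd1 (1.78; adjusted p = 0.0522 without CD4 AZA 1 and 0.0539 without nTreg AZA 1) and Il23r (1.85; 0.0533, 0.0525 and 0.0596 without CD4 PBS 1, 2 and 3, 0.0693 and 0.0683 without CD4 AZA 1 and 3, and 0.0507 without nTreg AZA 1). The size of the Il23r difference is not exact, given its dim signal under PBS. For Foxp3 the difference was −1.21 (SE 0.23, adjusted p = 0.0517) and for Cd8a 1.35 (SE 0.27, adjusted p = 0.0666), so with all arrays neither effect was shown to differ between the populations. Foxp3 passed without nTreg PBS 1 (−1.39, adjusted p = 0.0105) and Cd8a without nTreg PBS 3 (1.62, adjusted p = 0.00491).

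By list, glycolysis and cholesterol synthesis was more positive in nTregs (median 0.48, adjusted p = 8.22e-07; adjusted p = 0.509 with an estimated correlation). Of its 19 genes 0 passed limma (8 at an unadjusted p under 0.05, and 4 more positive adjusted over the list alone). The p53 target genes were more negative (−0.27, 0.0116; adjusted p = 0.509 with an estimated correlation), with Cdkn1a the 1 of 23 that passed (1 higher and 8 lower adjusted over the list alone). Lineage transcription factors (0.21, 0.0141), cytotoxic effectors (0.09, 0.0199) and mitochondrially encoded RNAs (−0.35, 0.0199) were called with the preset correlation (adjusted p = 0.509, 0.575 and 0.624 with an estimated correlation). By limma 0 of 23 lineage factors passed (8 at an unadjusted p under 0.05, 3 adjusted over the list alone) and 0 of 10 mitochondrial RNAs (3 at an unadjusted p under 0.05, 0 adjusted over the list alone). Of 20 cytotoxic effectors 1 passed, Klrd1 (5 adjusted over the list alone). The call was lost for p53 targets without nTreg PBS 2 (adjusted p = 0.0502) or 3 (0.0731) and for lineage factors without nTreg PBS 1 (0.118). Cytotoxic effectors lost it without CD4 PBS 3 (0.0516), CD4 AZA 1 (0.119), nTreg PBS 2 (0.0891), nTreg PBS 3 (0.0938) or nTreg AZA 3 (0.0723). Mitochondrially encoded RNAs lost it without CD4 PBS 3 (0.0793), CD4 AZA 1 (0.119), nTreg PBS 1 (0.134) or nTreg AZA 2 (0.101).

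The count of 45 became 16, 12 and 15 without CD4 PBS 1, 2 and 3, 10, 24 and 10 without CD4 AZA 1, 2 and 3, 69 and 29 without nTreg PBS 1 and 2, and 9, 18 and 15 without nTreg AZA 1, 2 and 3. Centring the arrays moved the median interaction over all genes from −0.04 to 0.09 and gave 89 genes, 92.1% of them more positive in nTregs against 71.1%. Over every row of the table, the split turned to 5 more positive and 8 more negative (38.5%), so it rests on the rows tested. In simulated data for the interaction, 58% of differences of 1 and 5% of differences of 0.5 were recovered.

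**Figure D3:**
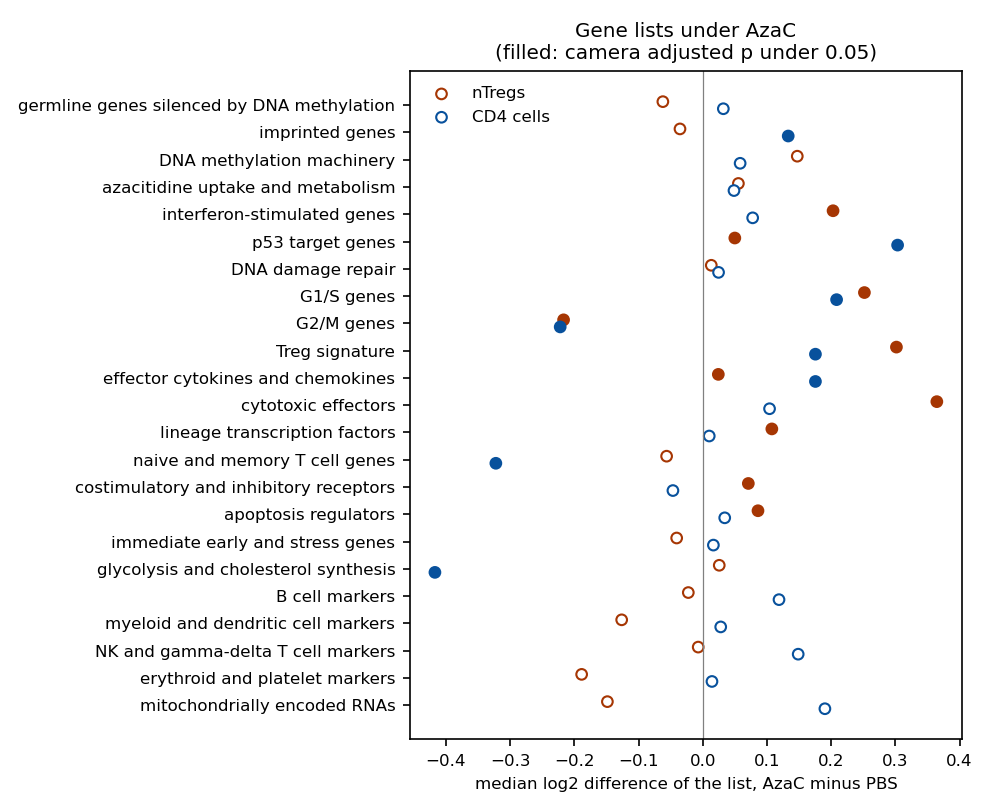
Median log2 difference between AzaC and PBS (horizontal axis) of the 23 tested gene lists (vertical axis) in nTregs and in CD4 cells; each point is the median over the measured genes of a list, filled where camera's adjusted p with the preset correlation was under 0.05. Glycolysis and cholesterol synthesis lies at −0.42 in CD4 cells and 0.03 in nTregs (−0.13 without nTreg PBS 1), and no filled point keeps its call with an estimated correlation.

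Under PBS, nTregs and CD4 cells differed in 1777 genes, 864 higher and 913 lower in nTregs. Foxp3 was 4.29 higher (SE 0.16), which follows from the sorting gate. Tigit, an inhibitory receptor, was 11.4-fold higher, at 9.74 ± 0.29 (SD, n = 3) against 6.24 ± 0.35 (log2 difference 3.51, SE 0.18, adjusted p = 5.48e-08). Cd40lg, the helper T cell ligand CD40L, was lower, at 7.92 ± 0.57 against 10.12 ± 0.26 (−2.19, SE 0.22, adjusted p = 2.09e-05). Other genes higher in nTregs were Muc3a (3.21), Fam183b (3.12), Frmd5 (3.08), Gbp2b (an interferon-induced GTPase, 2.98), Maf (a transcription factor of interleukin-10 expression, 2.81), Tnfrsf9 (4-1BB, 2.57), Ecm1 (2.56) and Enah (an actin regulator, 2.40). Lower ones were Atp8b4 (−2.66), Slc16a5 (a monocarboxylate transporter, −2.53), Pde3b (a phosphodiesterase, −2.34), Mctp2 (−2.26), Acpp (−2.24), Apol7e (−2.23), Igfbp4 (−2.21) and Pdlim4 (−2.20).

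Of 29 Treg signature genes, 23 were higher in nTregs under PBS (25 higher and 1 lower adjusted over the list alone; median 0.89, adjusted p = 7.40e-31; adjusted p = 0.00997 with an estimated correlation). Among them were Ikzf2 (Helios, 1.96), Tnfrsf4 (1.62), Il2ra (0.79) and Ctla4 (0.73). Of 23 costimulatory and inhibitory receptors, 11 were higher and 3 lower (13 and 4 adjusted over the list alone; median 0.53, adjusted p = 3.79e-06). Cd80 was 2.13 higher. Of 25 G2/M genes, 19 were lower (23 adjusted over the list alone; median −0.50, adjusted p = 2.97e-17), such as Prc1 (−0.87), Bub1b (−0.85) and Anln (−0.79). Of 19 naive and memory genes, 9 were lower (14 lower and 1 higher adjusted over the list alone; median −0.56, adjusted p = 4.29e-11), such as Actn1 (−1.48) and Ccr7 (a lymph node homing receptor, −1.17). Repair genes were lower as a list (22 genes, 1 higher and 3 lower, 1 and 7 adjusted over the list alone; median −0.24, adjusted p = 3.90e-05). These 5 lists kept their calls with an estimated correlation.

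Of 23 p53 target genes, 8 were higher in nTregs under PBS (11 adjusted over the list alone; median 0.35, adjusted p = 1.17e-07; adjusted p = 0.0565 with an estimated correlation), led by Cdkn1a (2.05, SE 0.12) and Plk2 (1.92). G1/S genes were lower (24 genes, 7 lower, 14 adjusted over the list alone; median −0.38, adjusted p = 2.88e-07; adjusted p = 0.0565 with an estimated correlation), such as E2f2 (−0.90) and Tk1 (−0.62). Glycolysis and cholesterol synthesis was lower (19 genes, 5 lower, 7 adjusted over the list alone; median −0.21, adjusted p = 2.76e-04; adjusted p = 0.398 with an estimated correlation), with Hmgcs1 at −0.97 and Cyp51 at −0.72. Without nTreg PBS 1 that list had an adjusted p of 0.176. Il10 (interleukin-10, 1.56), a gene of the Treg signature list, was higher. Outside the called lists, Gzmc (2.21) and Gzmb (1.43) were higher and Ctsw (−1.37) was lower. Cd4 was 0.83 lower on the log2 scale in nTregs (log2 difference −0.83, SE 0.15), and the B cell marker Cd79b was higher under PBS (0.80) and with AzaC (1.08).

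The count of 1777 became 1100 and 1042 without CD4 PBS 2 and 3, and 65 of 82 named genes that passed kept their call without each array in turn. Centring the arrays gave 583 higher and 1415 lower (29.2% higher, against 48.6%). The larger side turned with repeated quantile normalization (896 and 715) and with only the groups compared in the fit (371 and 277), so neither side prevailed.

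With AzaC, nTregs and CD4 cells differed in 1498 genes, 1013 higher and 485 lower in nTregs. Enah was 12.1-fold higher, at 9.83 ± 0.12 (SD, n = 3) against 6.23 ± 0.04 (log2 difference 3.60, SE 0.11, adjusted p = 2.1e-10). Frmd5 (3.41), Gzmc (3.10), Foxp3 (3.08) and Tnfrsf9 (3.06) were the next higher, and Acpp (−2.38), Apol7e (−2.11), Pdlim4 (−2.07), Cd40lg (−2.04) and Dapl1 (−1.86) the lowest. Of 29 Treg signature genes, 25 were higher and 1 lower (26 and 1 adjusted over the list alone; median 1.28, adjusted p = 5.21e-39; adjusted p = 0.00559 with an estimated correlation), including Tigit (2.99), Plagl1 (2.81) and Itgae (1.99). Of 23 costimulatory and inhibitory receptors, 13 were higher and 3 lower (15 and 3 adjusted over the list alone; median 0.63, adjusted p = 9.03e-10), with Cd86 at 1.99. G2/M genes were lower (17 of 25 lower, 22 adjusted over the list alone; median −0.54, adjusted p = 3.48e-17). So were naive and memory genes (10 of 19 lower and 2 higher, 13 and 2 adjusted over the list alone; −0.45, 1.54e-06) and repair genes (6 of 22 lower, 11 lower and 1 higher adjusted over the list alone; −0.29, 5.00e-05). These 5 lists too kept their calls with an estimated correlation.

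Cytotoxic effectors were higher in nTregs with AzaC (9 of 20 higher and 1 lower, 11 and 2 adjusted over the list alone; median 0.39, adjusted p = 7.02e-06; adjusted p = 0.124 with an estimated correlation), such as Serpinb9 (1.04) and Gzmb (1.02). G1/S genes were lower (5 of 24, 8 adjusted over the list alone; −0.26, 4.11e-06; adjusted p = 0.0769 with an estimated correlation). Immediate early and stress genes were higher (3 of 25, 6 adjusted over the list alone; 0.15, 0.00658; adjusted p = 0.0681 with an estimated correlation), with Fos at 1.15. P53 targets were higher as a list (5 of 23 higher and 1 lower, 6 and 1 adjusted over the list alone; 0.19, 0.00954; adjusted p = 0.369 with an estimated correlation), with Perp (0.86) and Fas (a death receptor, 0.78), while Cdkn1a was 0.43 higher (adjusted p = 0.0414). That call was lost without CD4 PBS 1 and 2 (0.0510 and 0.0593), CD4 AZA 1, 2 and 3 (0.0700, 0.116 and 0.113) and nTreg AZA 1, 2 and 3 (0.148, 0.0714 and 0.129). Glycolysis and cholesterol synthesis (1 of 19 higher, 1 adjusted over the list alone; 0.14, 0.0239; adjusted p = 0.559 with an estimated correlation) lost its call without CD4 AZA 1 (0.0827). Lineage transcription factors (4 of 23 higher and 1 lower, 6 and 1 adjusted over the list alone; adjusted p = 0.0482; adjusted p = 0.423 with an estimated correlation) had a median of 0.00397 and a mean of 0.23 and lost their call without 8 arrays: CD4 PBS 3 (0.0521), CD4 AZA 1 and 2 (0.0513 and 0.0508), nTreg PBS 1, 2 and 3 (0.0531, 0.0506 and 0.0523) and nTreg AZA 2 and 3 (0.0530 and 0.0783). Batf (1.40) and Maf were among the higher ones. Outside the called lists Cd8a (1.36), Cd8b1 (1.27), H2-Aa (1.15), Birc3 (0.95) and Birc2 (0.94) were higher in nTregs.

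The count of 1498 became 896 and 993 without CD4 AZA 1 and 3, 912, 959 and 900 without nTreg AZA 1, 2 and 3, and 2467 without nTreg PBS 1, which again enters through the shared spread. Of 72 named genes that passed, 53 kept their call without each array in turn. Centring gave 1118 higher and 357 lower (75.8% higher, against 67.6%). In simulated data for this comparison 83% of differences of 1 and 35% of differences of 0.5 were recovered.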

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

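Of the tests in this part, those of nTregs carried over into the CD4 cells, of CD8 T cells among the sorted nTregs and the tests of the p53 target genes (the array nTreg PBS 1 and signal near the top of the range) were chosen after the result was seen.

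The difference between the AzaC effects of nTregs and CD4 cells passed limma's interaction test for 23 named genes, which is what brought them here. More positive in nTregs were Atp8b4 (1.99), Plagl1 (1.92), Il23r (1.85), Klrd1 (1.78), Csn2 (1.77), Dusp4 (1.74), Nfkb2 (1.71), Ubd (1.48), Scin (1.42), Nfkbie (1.39), Il7r (1.20), Cd86 (1.10) and Birc2 (0.77). More negative were Cd80 (−1.69), Cox6b2 (−1.63), Cdkn1a (−1.62), Muc3a (−1.45), Dglucy (−1.36), Gpr155 (−1.33), Slc19a2 (−1.03), Ddias (−0.96), Cd81 (−0.94) and Dcxr (−0.79). The PBS signals of Il23r and Csn2 lay near that of the germline gene Asz1, so the sizes of their differences are not exact and have no rank. Atp8b4, Plagl1, Nfkbie, Il7r, Cd80 and Cdkn1a kept their call without each array in turn. Of the 23, 14, 15 and 15 lost theirs without CD4 PBS 1, 2 and 3, 16, 13 and 16 without CD4 AZA 1, 2 and 3, 3, 9 and 7 without nTreg PBS 1, 2 and 3, and 16, 13 and 14 without nTreg AZA 1, 2 and 3. By gene, Dcxr lost its call without each of the 12 arrays, Birc2, Dusp4 and Ubd without 11, Cd81, Ddias, Gpr155, Muc3a and Slc19a2 without 10, Cd86, Cox6b2 and Nfkb2 without 9, Csn2, Dglucy and Scin without 7, Il23r without 6 and Klrd1 without 2. The highest adjusted p reached was 0.152 for Birc2, without CD4 AZA 3.

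By list, the interaction medians that passed camera were 0.48 for glycolysis and cholesterol synthesis, 0.21 for lineage transcription factors, 0.0886 for cytotoxic effectors, −0.27 for p53 target genes and −0.35 for mitochondrially encoded RNAs. Limma passed 0 of 19, 0 of 23, 1 of 20 (Klrd1), 1 of 23 (Cdkn1a) and 0 of 10 genes of these lists, in the order given (8, 8, 7, 9 and 3 at an unadjusted p under 0.05). None of the 5 passed with an estimated correlation (adjusted p from 0.509 to 0.624) or with fry.

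Among the 17824 rows of the table without exactly 1 gene symbol, which the comparisons did not use, AzaC changed 15 in nTregs (10 higher, 5 lower) and 45 in CD4 cells (30 higher, 15 lower).

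Foxp3 rose in CD4 cells sorted as DsRed positive and negative for its reporter. A carry-over of nTregs from the AzaC cultures could raise it. The gate works against this, since the nTregs were DsRed negative and reporter positive, but how many passed it was not measured. At the Foxp3 signal of the nTregs with AzaC, a share of 8.17% would give the rise of 1.57. The 26 other genes at least 4-fold higher in nTregs under PBS would then rise by a median of 0.437. They rose by 0.138, with 23 of 26 below their prediction. Without each CD4 array in turn, 0.0868 to 0.151 was observed and 0.392 to 0.483 predicted. The 26 genes were picked once, on all arrays, against the CD4 PBS arrays from which both rises were counted. The fits without an array are thus no independent check. The prediction takes array signal as linear up to the bright Foxp3 signal of nTregs. A flattened Foxp3 signal would make the share and the predicted rises too large. It also takes these genes as unchanged by AzaC in CD4 cells, where Fam183b fell and Cdkn1a rose beyond its prediction. The shortfall argues against carry-over as the whole source only if both assumptions hold, and neither was tested. No single CD4 array carried the rise, since the highest adjusted p without 1 of them was 0.00219. A rise of Foxp3 mRNA in CD4 cells with AzaC, ahead of or without the reporter protein, remains a hypothesis. Carry-over remains open, in part or as the whole source.

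Cd8a and Cd8b1 rose in nTregs by a mean of 1.05. Without the deviating array nTreg PBS 1 the mean was 0.909, with an adjusted p of 0.00301 for Cd8a and 0.0547 for Cd8b1, so the array does not account for most of the rise. Cd8b1 stood at 0.63 (SE 0.15) without that array against 0.72 (SE 0.15) with it, and its call was lost as well without each nTreg AZA array, so it rests on a p near the threshold. CD8 T cells among the sorted nTregs could raise both genes, and the cytotoxic effectors that rose in the same arrays. The gate works against this, since it asks for the Foxp3 reporter and for no DsRed, the mark of the Treg-depleted T cells. Cd4 differed by 0.131 (SE 0.154) and Foxp3 by 0.354 (SE 0.164), which does not decide between such cells and expression of both genes by nTregs; with no CD8 T cell array the share cannot be bounded, so these explanations cannot be told apart.

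The 23 p53 target genes, a list fixed in advance, had a median interaction of −0.27, with Cdkn1a the only one that passed; the list's call was lost with an estimated correlation (adjusted p = 0.509) and without nTreg PBS 2 (0.0502) or nTreg PBS 3 (0.0731). The array nTreg PBS 1 does not account for it, since the median without it was −0.383 (adjusted p = 4.72e-06). Signal near the top of the range does not account for the list either, since 16 of the 23 lay below the 90th percentile of genes in nTregs under PBS. Of the 2218 genes above it, 33 rose with AzaC in nTregs (1.49%, against 1.42% of all genes), so such signals can still rise. These genes need not be as bright as Cdkn1a or Ccng1 (percentiles 98.9 and 99.8). Of the 7 targets above it, 5 differed by more than 0.1, among them Fas (0.38, SE 0.11) and Cdkn1a (0.33, SE 0.12). Ei24 and Sesn2 leaned on nTreg PBS 1, without which their interactions moved from 0.003 and 0.22 to −0.38 and −0.51. That 0 of the 7 passed limma's test (3 at an unadjusted p under 0.05) decides nothing at a rate of 1.49%. A full or partial loss of range stays open for the 7, while no biological explanation was tested.

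Other splits of the arrays were compared with the real groups. For the 4 comparisons of 3 arrays against 3, only 10 splits exist, too few for a share under 0.05. The real split was the only 1 of 10 with as many calls (448, 391, 1777 and 1498, highest other 0 in each). Each other split mixes the real groups, which shrinks the difference and adds it to the spread. Few calls were thus likely beforehand, and the 0 gives no rate of false calls. For the interaction, the real split was set beside others drawn at random. These mix the real groups too, so they give no rate of false calls either. Of the 100 splits in all, 2 gave as many calls as the real 45, the real one included. The other one gave 110 calls and kept the CD4 arrays apart by treatment, with the labels exchanged, and exchanged nTreg PBS 1 with nTreg AZA 2, so the real difference between the CD4 groups is part of its count, and what else adds to it is open.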

How the results depend on the processing

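The fit without both nTreg PBS 1 and CD4 PBS 3 was chosen after the results were seen, and the other alternatives before. Changes of sign of results that passed on neither side were not counted as reversals.

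Without each array in turn, the changed genes numbered 186 to 447 in nTregs (448 with all arrays), 164 to 1044 in CD4 cells (391), 9 to 69 for the interaction (45), 1042 to 1862 for nTregs against CD4 cells under PBS (1777) and 896 to 2467 with AzaC (1498). Called lists for the interaction numbered 3 to 5 (5 with all arrays). Of 284 gene results that passed, 195 kept their call without each array, and of 42 list results 30 did. No gene reversed. The list of glycolysis and cholesterol synthesis, with a median of 0.03 in nTregs and not called, ranged from −0.13 without nTreg PBS 1, called lower (adjusted p = 0.0104), to 0.20 without nTreg PBS 3.

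Without both deviating PBS arrays that median was −0.13 (adjusted p = 0.0139), and the counts were 678 in CD4 cells, 77 with 3 lists for the interaction and 2972 with AzaC; of the 448 nTreg calls, 341 were among the 533 made then. Array weights gave 1290 in nTregs, 1291 in CD4 cells, 401 for the interaction and 3500 with AzaC, and 447 of the 448 nTreg calls and all 391 CD4 calls were among them.

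With only the groups compared in the fit, 125 genes passed in nTregs, 648 between the cells under PBS and 2350 with AzaC. The test without moderation gave 238 in nTregs, 218 in CD4 cells, 6 for the interaction and 1120 under PBS. A fold change of at least 1.5 left 1019 under PBS and 904 with AzaC. Testing every row of the table gave 219 in nTregs, 255 in CD4 cells (145 higher, 110 lower) and 13 for the interaction (5 and 8), which turned the larger side in both of the latter. The filter on dim genes (12989 left) gave 76 genes and 3 lists for the interaction, repeated quantile normalization 3 lists, and centring 89 genes.

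Camera with an estimated correlation called 0 lists in nTregs, 0 in CD4 cells and 0 for the interaction, and 5 under PBS and 5 with AzaC. Fry called 0 for the interaction, against 9 in nTregs, 6 in CD4 cells, 12 under PBS and 11 with AzaC.

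A pairing of the samples by replicate number was not established: of 12 same-numbered pairs of arrays, 2 deviated together with a correlation over 0.1 (from −0.0986 to 0.187). The 6 pairs of nTregs and CD4 cells of a treatment had correlations of 0.0214 to 0.0915, with the own number the best in 12 of 12 choices. By design both populations were sorted from co-cultures, but the labels do not say which arrays share one. The 12 of 12 is a hint that same-numbered arrays of a treatment do, while the main fit took all arrays as independent. Between treatments the own number was best in 4 of 12. With the replicate number as a block, 451 genes passed in nTregs, 380 in CD4 cells, 40 for the interaction, 1826 under PBS and 1434 with AzaC, and 11, 8, 5, 9 and 11 lists. With same-numbered arrays of a treatment as a random block (correlation 0.0434), 444, 399, 58, 1935 and 1627 genes passed.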

Other observations

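The 3 gene sets of this part were chosen after the result that led to them was seen, with genes not seen before, and were then tested on the same arrays. The camera p-values given for them are not adjusted over the sets and comparisons. With an estimated correlation no adjusted p was computed, so camera p-values of 0.0337 and 0.0404 there are not calls.

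Rises of Nfkb2, Birc2 and Birc3 in nTregs with AzaC, and the more positive AzaC effect on Nfkbie there, led to a wider set of NF-kB feedback genes. Its 16 genes shifted upward in nTregs (median 0.41, camera p = 2.22e-08, p = 0.0053 with an estimated correlation), and 6 of them passed among all genes: Relb (1.17), Bcl3 (0.81), Tnip1 (0.72), Traf1 (0.66), Tank (0.54) and Nfkbia (0.42). The count fell to 3 without CD4 PBS 1, CD4 AZA 3 or nTreg AZA 2 and to 2 without nTreg AZA 1 or nTreg AZA 3, while the p of the set stayed between 6.3e-09 and 5.17e-07 without each array. Fits without a CD4 array left the median at 0.41, since such an array enters only through the shared spread. In CD4 cells the median was 0.06 (p = 0.263), and the interaction had a median of 0.38 (p = 0.000159, and 0.0337 with an estimated correlation), with 0 of the 16 passing limma (9 at an unadjusted p under 0.05). Higher NF-kB activity in nTregs with AzaC is a hypothesis, since only mRNA was measured, on the arrays that led to the set.

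Falls of Scd1 and of cholesterol synthesis genes in CD4 cells led to a set of 21 further sterol and fatty acid synthesis genes. It shifted downward in CD4 cells (median −0.37, camera p = 8.66e-08, p = 0.0836 with an estimated correlation), with Stard4 (−0.78), Acss2 (−0.77), Nsdhl (−0.66), Msmo1 (−0.60) and Mvk (−0.49) lower and Lpin1 (0.64) higher (Lpin1 lost without CD4 PBS 1, 2 and 3 or CD4 AZA 2 and 3, adjusted p 0.0551 to 0.0899). The 5 lower calls became 1 without CD4 PBS 1, 2 without CD4 PBS 2, 0 without CD4 PBS 3, CD4 AZA 1 or CD4 AZA 3, 3 without CD4 AZA 2 or nTreg AZA 1, and 10 without nTreg PBS 1; the p of the set stayed between 8.97e-09 and 7.04e-06. In nTregs the median was 0.22 (p = 0.015, and 0.396 with an estimated correlation; Elovl6 passed, at 0.47, and lost its call without 11 of the 12 arrays). That p was 0.748 without nTreg PBS 1 and between 0.00134 and 0.0257 without each other array. Scd1 itself fell in nTregs (−0.79, adjusted p = 0.00604), and without nTreg PBS 1 the fixed list of glycolysis and cholesterol synthesis was called lower there (median −0.13, adjusted p = 0.0104), so no direction is claimed for nTregs. The interaction had a median of 0.44 (p = 5.88e-09, and 0.064 with an estimated correlation), with 0 of the 21 passing limma (12 at an unadjusted p under 0.05). Lower sterol regulation in CD4 cells is a candidate explanation, untested at the protein level.

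Falls of Aldoc and P4ha2 in CD4 cells led to 19 further hypoxia-induced genes. They shifted downward in CD4 cells (median −0.54, camera p = 9.91e-10, p = 0.0404 with an estimated correlation), with Pdk1 (−0.81) the only one past the threshold; its call was lost without each of the 6 CD4 arrays and the 3 nTreg AZA arrays (adjusted p 0.0719 to 0.212). Lower calls numbered 0 without CD4 PBS 2 or 3, CD4 AZA 1 or 3, or any nTreg AZA array, 4 without nTreg PBS 3 and 10 without nTreg PBS 1. The median in nTregs was −0.28 (p = 0.00783, 0.316 without nTreg PBS 3, and 0.319 with an estimated correlation), but the only gene of the set that passed there rose: Bhlhe40 (1.15, adjusted p = 0.0177; 0.0685, 0.0808 and 0.0646 without nTreg AZA 1, 2 and 3). The interaction (p = 0.00539, and 0.298 with an estimated correlation) was lost without CD4 PBS 3 (0.0626) or nTreg PBS 1 (0.0643), and 0 of the 19 passed limma there (2 at an unadjusted p under 0.05). The 2 of 19 were below the share of all genes at that level (3871 of 22180). Fewer cells in AzaC cultures could leave more oxygen in the medium, but no cell counts are part of these data, so this stays untested.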
